A study of Mus musculus with 6 samples.

How the data were processed

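RNA of mouse granulosa cells was measured in 6 libraries, 3 labelled wild type and 3 labelled Gm12840-/-, made with the TruSeq RNA kit, per the labels' protocols. This kit does not mark strand, so reads of a gene and of an antisense gene cannot be told apart. The authors deposited 1 table of FPKM values per library, with 54551 genes and their coordinates, exon length and biotype. HISAT2 2.0.5 and mm10 are named in the submitters' processing notes. The counter, the annotation release and the scaling are not given in the sources used here. Of 53706 gene IDs shared with GENCODE M21, 52105 had the same coordinates. Gene names were those of the deposited tables, where 750 features had none.

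The deposited FPKM values times gene length were whole multiples of 1 step per library in 100% of values, within 0.01 reads, so read numbers were recovered. Recovered depth ran from 16392098 to 19465847 reads. The authors' FPKM used library totals that were 0.894 to 1.12 times the recovered reads. These totals were proportional to median-of-ratios size factors to within 1.3e-07%. Intervals on reads are exact Poisson or binomial intervals at 95%, and cover counting error only. Where all libraries of a group had 0 reads, the floor was 3 reads over the group. Libraries of the same label differed by more than sampling noise in a chi-square test over genes with at least 20 reads. None was therefore taken for a second copy of another library of its label. Pairs of different labels were not put to this test. It does not show that the libraries came from separate animals.

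Groups were taken from the titles of the samples. The tests, alternatives, gene lists and rule for named genes were set before the data were examined. That plan assumed deposited counts, with limma for normalized values. The tables hold FPKM, so limma 3.58.1 in R 4.3.3 was used on log2(FPKM + 1), with a trend in the prior variance and genotype as the only term. A fold change on this scale understates the change of low genes. Genes entered with an FPKM over 1 in at least 3 libraries, and p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gm12840 fell under this filter and was tested in the fit without one. Single values were compared by an exact permutation test, where 3 against 3 gives no p under 0.1.

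The 35 gene lists held genes of ovulation, steroid synthesis, other pathways, RNA quality and other ovarian cells. Lists with at least 5 tested members, 33 in all, were tested by camera with a preset correlation of 0.01, then by camera with an estimated correlation and by fry. The rule for named genes took Gm12840, the called genes with the largest changes, up to 4 called members of each list or otherwise the 2 with the smallest p, called neighbours within 1 Mb, and the 3 most abundant genes of the wild-type libraries. With 0 genes called, the text names some of the remaining genes that this rule took. Genes outside it were chosen after their values were seen. Values of Gm23935, 1 of the 3 most abundant, are uncertain, since it is a short feature whose reads near-identical copies can share.

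The test was run on simulated negative binomial counts at the real means and depths, with an assumed dispersion of 0.05 and 200 changed genes. It recovered 46 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, with 13 false calls. A second test raised 200 genes together in the real values, at 4 fold changes up to 16-fold, and recovered 0 of 50 at 2-fold and 14 of 50 at 4-fold. Alternatives set beforehand were pseudocounts, filters, median-of-ratios factors, library totals, limma-voom, the replicate number as a block, protein-coding genes and leaving out each library. Alternatives added after the data were examined were leaving out replicate 3 of both groups, the length slope as a covariate, and a correction for length and GC content by local regression. Transcript GC content was known for 97.1% of genes. Figures were drawn with matplotlib 3.10.9.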

Results

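Granulosa cells, the follicle cells that surround the oocyte and make oestradiol and progesterone, were profiled by RNA sequencing from the ovaries of C57BL/6 mice on postnatal day 21. The mice had received 5 IU of PMSG, a gonadotropin that drives follicle growth, for 48 h and then 5 IU of hCG, which stands in for the ovulatory surge of luteinizing hormone (LH), for 6 h. The labels give 3 wild-type libraries and 3 libraries of Gm12840-/- mice. The depth recovered from the deposited values was 16609477, 17997837 and 19465847 reads in the libraries labelled wild type 1 to 3. It was 16722828, 16392098 and 17020427 reads in those labelled knockout 1 to 3. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples.

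The first question was whether Gm12840, the targeted gene, was lower in the libraries labelled knockout. Gm12840 (ENSMUSG00000086320) is annotated as a lincRNA on the plus strand of chromosome 4, from 117700188 to 117700923 in mm10. Its 2 exons run from 117700188 to 117700304 and from 117700414 to 117700923, 627 nt in all. No other annotated gene overlaps it, and the nearest is Dmap1, 17915 bp away. Gm12840 stood at 1.83, 0.566 and 0.365 FPKM in the libraries labelled wild type 1 to 3. In the libraries labelled knockout 1 to 3 it stood at 0.426, 0.611 and 1.45 FPKM. These values rest on 17, 6 and 5 reads against 5, 7 and 14 reads. The group means were 0.919 ± 0.792 and 0.829 ± 0.546 FPKM (SD, n = 3 each), and the exact two-sided permutation p was 1 where 0.1 is the smallest possible. The log2 fold change on the log2(FPKM + 1) scale was -0.03, with a 95% interval of -0.91 to 0.84 and an adjusted p of 0.988 by limma. At such low values, complete loss in every library labelled knockout would also lie within this interval. This fit therefore cannot tell complete loss from no change, and the comparison rests on the reads. Over the pooled reads the ratio of knockout to wild type was 1.00, with an exact 95% interval of 0.564 to 1.77 that covers counting error only. The library labelled wild type 1 held 17 of the 28 wild-type reads, and without it the ratio was 1.77 (0.843 to 3.96). Without knockout 3 it was 0.70 (0.324 to 1.42). The labels do not say which part of the gene was deleted, so reads outside a deleted part would not check the genotype. Because the targeted gene was not lower, the groups are named below as the libraries labelled wild type or knockout, and every direction between them rests on those labels.

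**Figure D1:**
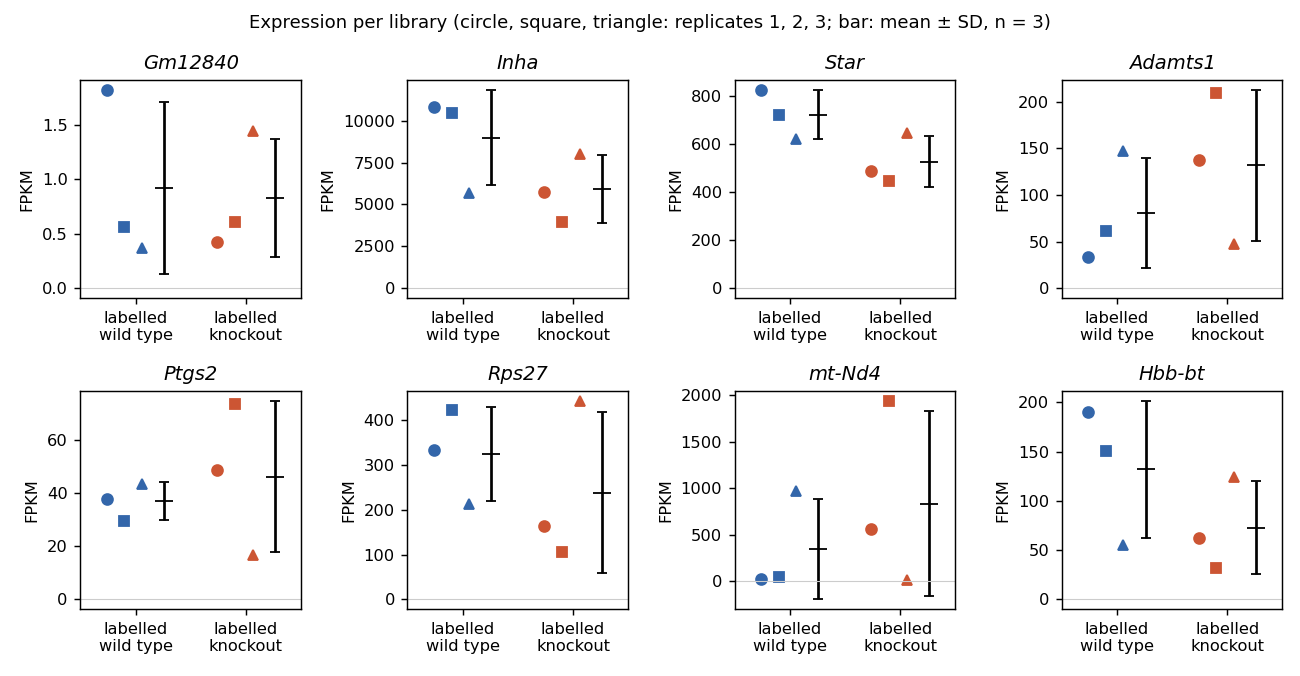
FPKM of 8 genes in each library, with replicates 1, 2 and 3 as circle, square and triangle, and the group mean ± SD as a bar (n = 3). Gm12840 stood highest in the library labelled wild type 1, at 1.83 FPKM, and next in the library labelled knockout 3, at 1.45 FPKM.

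The design's only comparison asked which genes differed between the libraries labelled knockout and wild type. Sult1e1, an oestrogen sulfotransferase, stood at 1385 ± 426 FPKM in the libraries labelled wild type and 763 ± 108 in those labelled knockout (SD, n = 3 each). Star, which carries cholesterol into mitochondria for steroid synthesis, stood at 723 ± 103 and 527 ± 106 FPKM. Inha, the inhibin alpha subunit, was among the 3 most abundant genes of the wild-type libraries, at 8992 ± 2855 against 5906 ± 2036 FPKM. None of these genes passed the test, with adjusted p = 0.993 by limma for each.

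Of 12495 genes tested, limma called 0 at an adjusted p under 0.05, so 0 were higher and 0 lower. At an unadjusted p under 0.05 it gave 91 genes, 0.728% of those tested where chance gives 5%. limma-voom on the recovered reads also called 0, with 75 genes at an unadjusted p under 0.05. The groups did not overlap in 441 genes, 3.53% of those tested, where chance gives 10%. These chance shares are averages over splits and need not hold for a single split of libraries whose genes move together. Each labelled group held libraries from both sides of the main difference between libraries, which widens the spread within groups. The median 95% interval reached 0.735 on the log2 scale to either side of the estimate. When 200 genes were raised together in the real values, the test recovered 0 of 50 at 2-fold, 14 of 50 at 4-fold, 36 of 50 at 8-fold and 41 of 50 at 16-fold. It also called 2 genes that were not raised. Raising many genes together eases the adjusted threshold for each, so these rates may overstate what the test could see among few changed genes. With the libraries labelled wild type 3 and knockout 3 both left out, an alternative added after the data were examined, limma called 3451 genes, of which 1409 were higher and 2042 lower. The remaining libraries are divided by label along the main difference between libraries, described below, so these calls cannot be credited to the genotype. With each library's length slope as a covariate, also added after the data were examined, limma called 1 gene, Mir1291.

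Genes induced by the LH surge showed no common direction. Of 32 tested genes in this list, 15 had a positive and 17 a negative log2 fold change, and 0 were called over all genes or adjusted over the list alone. Pgr, the progesterone receptor that follicle rupture requires, stood at 5.85 ± 1.88 FPKM in the libraries labelled wild type and 3.20 ± 2.53 in those labelled knockout (n = 3, adjusted p = 0.993 by limma). Ereg, an EGF-like ligand, stood at 35.5 ± 2.20 and 53.2 ± 29.0 FPKM. Ptgs2, the inducible prostaglandin synthase, stood at 37.0 ± 6.99 and 46.2 ± 28.4 FPKM. Tnfaip6, a hyaluronan-binding matrix protein, stood at 212 ± 31.8 and 169 ± 73.3 FPKM. Ereg, Ptgs2 and Tnfaip6 were chosen after their values were seen. Camera did not call this list (adjusted p = 0.72), nor the lists of cumulus expansion (0.111), EGF-like ligands with ERK feedback (0.998) or progesterone receptor targets (0.79). Among their members, Phlda1 stood at 13.0 ± 1.29 against 7.82 ± 2.29 FPKM and Itih2 at 5.92 ± 3.15 against 9.38 ± 1.18 FPKM, neither called.

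Steroidogenesis genes were lower in the libraries labelled knockout by camera at a preset correlation of 0.01. Of 17 tested members 13 were negative, the median log2 fold change was -0.32, and the adjusted p was 0.0121. The adjusted p = 0.813 with an estimated correlation. The list's median deviation was 0.31, 0.21 and -0.06 in the libraries labelled wild type 1 to 3, and -0.21, -0.40 and 0.08 in those labelled knockout 1 to 3, on the log2 scale. Cyp19a1, the aromatase that makes oestradiol, stood at 8.99 ± 4.79 and 4.31 ± 1.71 FPKM (SD, n = 3 each). Stard3 stood at 15.3 ± 1.17 and 11.8 ± 1.71 FPKM. No member was called over all genes or adjusted over the list alone. Camera did not call cholesterol biosynthesis (adjusted p = 0.72), preovulatory granulosa genes (0.829) or luteinization genes (0.662). Cyp11a1, which makes pregnenolone from cholesterol, stood at 522 ± 166 and 370 ± 109 FPKM.

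Genes of protein synthesis and respiration moved together across libraries. All 50 tested cytosolic ribosomal protein genes were negative by a median of -0.44, with camera's adjusted p = 0.000174 and adjusted p = 0.813 with an estimated correlation. Rps27 stood at 324 ± 105 FPKM in the libraries labelled wild type and 238 ± 180 in those labelled knockout. Of 33 nuclear genes of oxidative phosphorylation, 32 were negative, with camera's adjusted p = 0.001 and adjusted p = 0.813 with an estimated correlation. Ribosomal protein genes took 13.1%, 9.57% and 4.58% of the reads in the libraries labelled wild type 1 to 3, and 6.20%, 3.69% and 12.1% in those labelled knockout 1 to 3. No member of either list was called over all genes or adjusted over the list alone.

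Mitochondrially encoded genes, a sign of RNA or sample quality, were higher in the libraries labelled knockout by camera (adjusted p = 0.0317), with adjusted p = 0.813 with an estimated correlation. Their share of the reads was 0.198%, 0.286% and 2.05% in the libraries labelled wild type 1 to 3, and 1.47%, 4.13% and 0.125% in those labelled knockout 1 to 3. mt-Nd2 stood at 68.1, 71.6 and 914 FPKM against 519, 2159 and 81.7 FPKM. All 11 tested replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were negative (camera's adjusted p = 0.000294, adjusted p = 0.813 with an estimated correlation). Their median deviation was 0.37, 0.65 and -0.35 in the libraries labelled wild type 1 to 3, and -0.72, -0.60 and 0.49 in those labelled knockout 1 to 3. Circadian clock genes were positive in 10 of 11 (camera's adjusted p = 0.0317, adjusted p = 0.813 with an estimated correlation). The clock list's median deviation was -0.36, -0.042 and -0.015 in the libraries labelled wild type 1 to 3, and 0.28, 0.33 and -0.36 in those labelled knockout 1 to 3. Nr1d2 stood at 2.40 ± 0.546 and 4.68 ± 2.24 FPKM. Immediate early and heat shock genes were not called (adjusted p = 0.273).

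Markers of other ovarian cells were measured beside these groups. All 12 tested markers of stroma, pericytes and smooth muscle were positive, by a median of 0.45 (camera's adjusted p = 2.14e-08, adjusted p = 0.813 with an estimated correlation). Their median deviation was -0.147, -0.483 and -0.0784 in the libraries labelled wild type 1 to 3. It was 0.399, 0.348 and -0.0717 in those labelled knockout 1 to 3, so knockout 3 was close to wild type 3. Col1a2, a fibrillar collagen chain, stood at 5.31 ± 0.829 and 7.92 ± 1.21 FPKM. Theca markers (adjusted p = 0.0317) and endothelial markers (0.0435) were higher by camera, and oocyte markers (0.00762) and erythroid markers (0.0114) lower, each with adjusted p = 0.813 with an estimated correlation. The groups overlapped in the theca list's median deviation, at 0.136 in wild type 1 and -0.0292 in knockout 3. They also overlapped in the endothelial list's, at 0.0502 in wild type 1 and -0.0594 in knockout 2. The oocyte list's median deviation was 0.45, 0.36 and -0.34 in the libraries labelled wild type 1 to 3. It was -0.17, -0.59 and 0.17 in those labelled knockout 1 to 3, so replicate 3 of both groups ran against the stated direction. Eng, an endothelial receptor, stood at 3.38 ± 1.18 and 5.92 ± 1.41 FPKM. Hbb-bt, a beta globin, stood at 132 ± 69.3 and 72.8 ± 47.2 FPKM. Haemoglobin genes took 0.308%, 0.203% and 0.0525% of the reads in the libraries labelled wild type 1 to 3, and 0.0649%, 0.0403% and 0.246% in those labelled knockout 1 to 3. Leukocyte markers (adjusted p = 0.829), ovarian surface epithelium markers (0.121) and granulosa cell identity genes (0.547) were not called by camera. Foxl2, a granulosa cell transcription factor, stood at 42.8 ± 2.73 and 34.6 ± 12.2 FPKM. The oviduct list had 1 tested member and the adipocyte list 2, too few for the test.

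**Figure D2:**
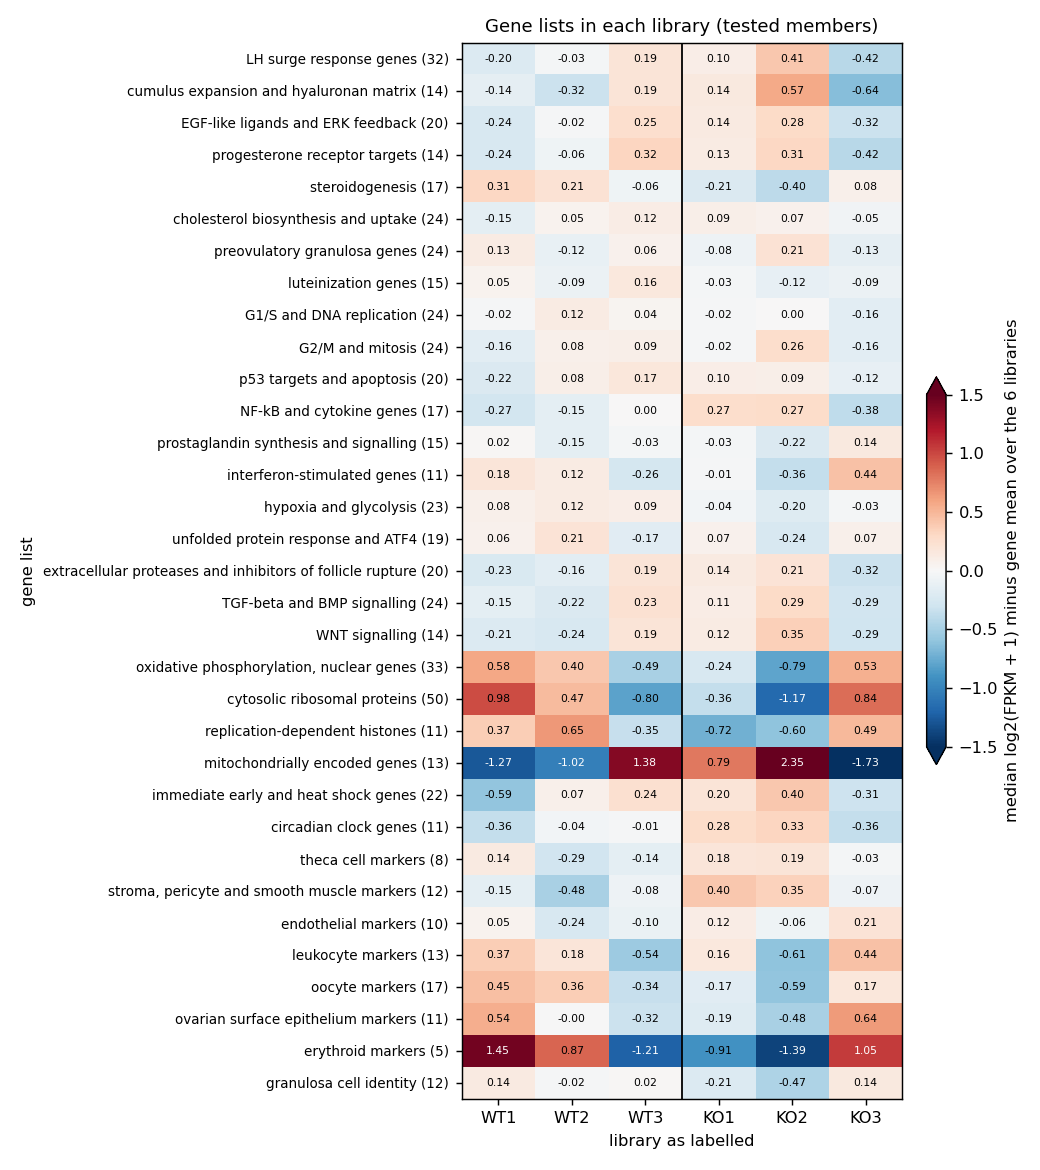
Median deviation of each gene list (rows, tested members in brackets) in each library (columns as labelled), in log2(FPKM + 1) from each gene's mean over the 6 libraries, with colours ending at 1.5. The median of the mitochondrially encoded genes ran from -1.73 in the library labelled knockout 3 to 2.35 in the library labelled knockout 2.

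The remaining lists gave no call by camera. Their adjusted p-values were 0.667 for G1/S and DNA replication, 0.998 for G2/M and mitosis, 0.478 for p53 targets and apoptosis, and 0.273 for NF-kB and cytokine genes. They were 0.664 for prostaglandin synthesis, 0.79 for interferon-stimulated genes, 0.0886 for hypoxia and glycolysis, and 0.898 for the unfolded protein response. They were 0.314 for extracellular proteases, 0.838 for TGF-beta and BMP signalling, and 0.41 for WNT signalling. Slc2a1, a glucose transporter, stood at 51.8 ± 3.21 and 38.2 ± 7.06 FPKM. Mmp11, a matrix metalloprotease, stood at 34.2 ± 7.26 and 49.8 ± 3.33 FPKM. In all, 11 of 33 tested lists passed camera at a preset correlation, 0 passed it with an estimated correlation, and 0 passed fry. Camera's count was 5 without the library labelled wild type 1, 6 without knockout 1, and 7 without wild type 3 or without knockout 2. An alternative added after the data were examined left out replicate 3 of both groups. It sets libraries at opposite ends of the first principal component, described below, against each other. Camera at the preset correlation then also called cumulus expansion (adjusted p = 0.0125) and NF-kB and cytokine genes (0.023), both higher. TGF-beta and BMP signalling (0.0436) was called too, also higher. Camera no longer called steroidogenesis (0.138), theca markers (0.412) or endothelial markers (0.51). Values with an estimated correlation are not given for this fit.

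Neighbours of Gm12840 were compared because a deletion can change nearby genes. Of 38 tested genes within 1 Mb, 11 were positive and 27 negative, by a median of -0.20. Kif2c, a mitotic kinesin, had the smallest unadjusted p in limma, 0.119. limma called 0 of the 38, with 0 at an unadjusted p under 0.05, which 0.728% of all tested genes reached. With 0 genes called, Fisher's exact test against the other genes is uninformative. limma-voom called 0 of all tested genes. With replicate 3 of both groups left out, limma called 14 of the 38 neighbours, in a fit that called 27.6% of all tested genes.

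Libraries of one labelled genotype were not more alike than libraries of different labels. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.895 to 0.980 within the libraries labelled wild type. It was 0.814 to 0.954 within those labelled knockout and 0.828 to 0.983 between the groups. The first principal component held 83.3% of the variance. Its scores were -50.1, -31.1 and 42.1 in the libraries labelled wild type 1 to 3, and 23.3, 70.8 and -55.0 in those labelled knockout 1 to 3. Short genes differed between libraries, and the slope of log2 values on log2 gene length ran from -0.181 in the library labelled wild type 1 to 0.280 in the library labelled knockout 2.

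**Figure D3:**
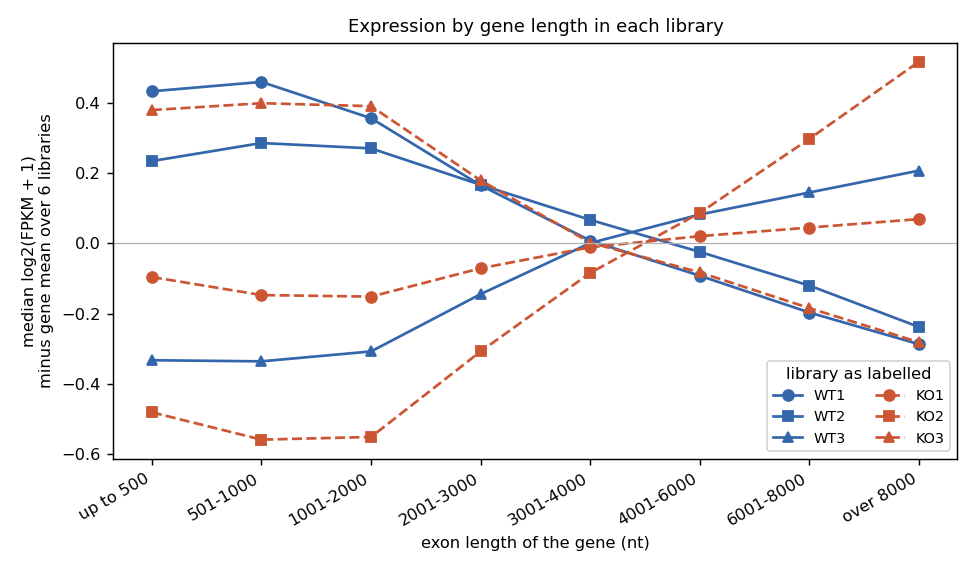
Median deviation of genes in 8 classes of exon length (horizontal axis, nt) from each gene's mean over the 6 libraries (vertical axis, log2(FPKM + 1)), with 1 line per library. Genes in the shortest class stood at 0.43 in the library labelled wild type 1 and at -0.48 in the library labelled knockout 2.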

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

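The alternatives that leave out replicate 3 of both groups, add the length slope or correct length and GC content were chosen after the results were seen. limma called 0 genes in the comparison under each alternative set beforehand that was run, and in the correction for length and GC content. With replicate 3 of both groups left out it called 3451 genes (1409 higher, 2042 lower) and 14 of the neighbours of Gm12840. Of the 3451, 3449 changed in the direction of their loading on the first principal component. This agreement was fixed by the choice of libraries. It left wild type 1 and 2 (scores -50.1 and -31.1 on that component) against knockout 1 and 2 (23.3 and 70.8). The calls of this alternative therefore cannot be credited to the genotype. With the length slope as a covariate limma called 1 gene, 1 higher, and the cause was not tested. Camera's count of lists, 11, was 7 with no filter, which tests more genes, and 5 to 10 when 1 library was left out. It was 5 without the library labelled wild type 1, 6 without knockout 1, and 7 without wild type 3 or without knockout 2. It was 0 by fry and 0 by camera with an estimated correlation. With the replicate block, 0 genes and 11 lists passed. Deviations of same-numbered libraries had correlations of -0.422, -0.672 and -0.894, and 0 of 6 libraries correlated best with their own number. These values gave no sign of pairing by number. The first principal component, with 83.3% of the variance, weighs on them, so they cannot exclude a weaker pairing. Median-of-ratios factors are proportional to the authors' own scaling, so that setting left the calls and counts as they were and is no independent check. Library totals moved the median log2 fold change of all genes from -0.04 to 0.04.

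The log2 fold change of Gm12840, -0.03, turned to 0.0047 with library totals, 0.035 with limma-voom and 0.16 with the length slope, and ran from -0.27 to 0.28 when 1 library was left out. It was -0.47 with replicate 3 of both groups left out, with an adjusted p of 0.515 by limma. It was not called in any alternative that tested it, with adjusted p-values from 0.515 to 1. The filter at 1 read per 1e+06, protein-coding genes only, and the length and GC correction gave it no value. Other signs turned among genes that were not called, and the cause was not tested. With the length slope, Bst2 turned to 0.19, Fabp4 to 0.033, Rplp1 to 0.16, mt-Co1 to -0.43, mt-Nd4 to -0.60, mt-Cytb to -0.36, Klf17 to -0.28, Ptgs2 to -0.26, Vcan to -0.013 and Amh to 0.19. With length and GC content corrected, Ptgs2 turned to -0.058. With replicate 3 of both groups left out, Tppp3 turned to -0.085 and Gm23935 to -0.76. When 1 library was left out, Bst2 ran from -1.01 to 0.14, Tppp3 from -0.10 to 0.85, Fabp4 from -0.32 to 0.063, Gm23935 from -0.37 to 0.52 and Rplp1 from -1.34 to 0.10. mt-Co1 ran from -0.34 to 2.02, mt-Nd4 from -0.33 to 3.32, mt-Cytb from -0.20 to 2.62, Klf17 from -0.27 to 0.57, Tnfaip6 from -0.66 to 0.0055, Ptgs2 from -0.34 to 0.69, Vcan from -0.13 to 1.00, Malat1 from -0.014 to 1.20 and Amh from -0.86 to 0.19. Of 1577 values of 88 genes under the alternatives, some of them genes chosen after their values were seen, 1500 kept their sign and stayed uncalled, 43 became called and 34 turned sign. Of the 43, 42 came from leaving out replicate 3 of both groups. Count-model fits in edgeR and DESeq2, and the test against a fold change of 1.5 in edgeR, were planned and left out by choice, since the deposited unit is FPKM. The recovered reads were used with limma-voom only.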

Other observations

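All tests of explanations in this part, and the genes named first, were chosen after the results were seen. Mir1291, a microRNA gene of 117 nt on chromosome 15 from 98519762 to 98519878, had 0 reads in the libraries labelled wild type and 7, 8 and 7 in those labelled knockout. Against a floor of 3 reads over the group it was 7.91-fold higher, with an adjusted p of 0.0893 by limma that misses the threshold. That fold leaves out the counting error of its own reads, so it is no lower bound. With 7 or 8 reads per library, the value of this short feature is uncertain. The labelled split held 2 tested genes with 0 reads in one group and at least 2 in each library of the other, and the other splits held 0 to 13. Its adjusted p ran from 0.0083 with the length slope as a covariate to 1 over the alternatives. Stc1, a secreted glycoprotein, stood at 1.71 ± 0.638 FPKM in the libraries labelled wild type and 4.36 ± 1.15 in those labelled knockout (SD, n = 3 each). Igfbp4, an IGF-binding protein, stood at 24.3 ± 5.64 and 41.0 ± 11.3 FPKM. Neither was called (adjusted p = 0.993 by limma). mt-Nd4 ranged 172-fold over the 6 libraries, and Adamts1, a protease of the ovulating follicle, 6.21-fold.

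The labelled split of the 6 libraries called 0 genes, and the highest of the other splits called 6941. A count of 0 is reached by all 10 splits by construction, so this comparison tests nothing. The split with 6941 genes sets the libraries labelled wild type 1, wild type 2 and knockout 3 against the others, which points to a structure of the samples. The labelled split gave 11 lists past camera's threshold, and the highest other gave 14. Of the 10 splits, 5 gave 11 or more lists, the labelled one included. The splits are too few for a share under 0.05.

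No gene separated the labelled genotypes while the libraries differed strongly among themselves, and the library labelled knockout 3 correlated at 0.983 with wild type 1 and at most at 0.924 with another labelled knockout. The genotype as labelled was tested in the main comparison, which called 0 of 12495 genes. As the cause of the main difference between libraries it is argued against by the first component. Wild type 3 (42.1) and knockout 3 (-55.0) lay on the opposite side of it from the rest of their labelled groups. A smaller effect of the genotype, or one hidden by wrong labels, stays open. Length and GC bias as the whole cause is argued against only as far as its correction removed it. After that correction the strongest split still called 5796 of 11828 genes. The first component held 81.6% of the variance against 83.3% before, which are shares of different totals. Its scores ran from -44.8 to 52.1 over these genes, against -55.0 to 70.8 over 12495 genes before. A linear fit on length and GC content took up 30% of the variance of the gene loadings before correction. Length and GC content thus went with part of this component. A bias beyond annotated gene length and mean GC content was not removed and stays open. A different share of granulosa cells also stays open. Slopes of other cell types' markers on the first component after that correction lay up to 0.844 apart. This rests on 5 erythroid genes (-0.765), and the intervals of the other lists overlap. Exchanged labels of replicate 3 in both groups stay open as well. Gm12840 was 3.20 times higher per read in the library labelled knockout 3 than in wild type 3 (95% interval 1.09 to 11.4, counting error only). Genes of matched length and reads also tended higher there, with a median log2 ratio of 0.603 against 1.74 for Gm12840 (pseudocount 0.1). Of 567 such genes, 20.3% had as high a ratio, so this comparison cannot decide. RNA quality or handling stays open too. Slopes after that correction were 1.25 for mitochondrially encoded genes (95% interval 0.203 to 2.15) and 0.509 for immediate early and heat shock genes (0.175 to 0.663). They were 0.286 for clock genes (0.0783 to 0.309) and -0.102 for replication-dependent histones (-0.153 to -0.042). Pathway lists moved as well, with 0.238 for LH surge response genes (0.0876 to 0.366) and -0.625 for cytosolic ribosomal proteins (-0.681 to -0.472). The slopes therefore do not single out RNA quality. Intervals on slopes resample the genes of a list, which move together, and not the libraries, so they give no uncertainty over samples.

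Gm12840 was not lower in the libraries labelled knockout, and technical explanations were weighed by its reads. A complete loss hidden by low depth is argued against by 26 reads in the libraries labelled knockout, at least 5 in each. Reads of an overlapping annotated gene are argued against by the 0 annotated genes that overlap its span. Whether the deletion spares part of the transcript, or whether labels are wrong, stays open, and no biological explanation was tested. An exchange of replicate 3 between the groups would still leave 5, 5 and 7 reads in wild type 3, knockout 1 and knockout 2. The other group would then hold 17, 6 and 14 reads in wild type 1, wild type 2 and knockout 3. Gm12840 would thus have fewer reads in total, but not none, in the exchanged knockout group. A first comparison of such sums with those of matched genes could not decide whether labels were exchanged. It was replaced by the comparison of knockout 3 with wild type 3 alone, which could not decide either.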
